A study of Mus musculus with 12 samples.

How the data were processed

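Thymic epithelial cells form the stroma in which T cells develop. Per the labels' protocols, thymuses of mice 2 months of age were dissociated with Liberase TH and DNase, cortical (cTEC) and medullary (mTEC) epithelial cells were separated by flow cytometry into lysis buffer, and RNA was purified with a NucleoSpin XS kit. Libraries were made with the SMARTer low-input kit, version 4 per the labels, which does not mark strand, so reads of a gene and of an antisense partner cannot be told apart.

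The authors deposited 1 table of raw read counts per gene, with gene symbols and no other identifiers, for all 12 libraries. Per the submitters' processing notes, STAR, HTSeq, edgeR and the mouse build mm9 were used. Tool versions, the gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. The annotation at hand was GENCODE M21 on GRCm38, a different build, so no coordinates are given. That annotation served only for the length of each gene's longest transcript and its GC content, matched by symbol for 98.01% of the genes tested.

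The table held 31332 genes, each of the 12 columns matched 1 sample, and 17268 genes passed edgeR's filterByExpr by group. Total counts ran from 4804697 to 11159013 per library, and 1 count corresponded to between 0.0898 and 0.194 CPM. Within groups, the correlation of log CPM between libraries ran from 0.9665 to 0.9899 across genes, and chi-square per degree of freedom between 3.08 and 12.1, so no library was a copy of another. Levels are given as CPM, the counts of a gene relative to the library total, scaled by TMM factors, computed from the deposited counts. Counting intervals are not given, because reads without molecular identifiers are not independent molecules.

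Samples were placed in 4 groups of 3 by the cell type and genotype in the labels. Libraries carry the numbers 1 to 12, and no number is shared between groups, so no pairing was used. The labels do not say whether the 3 libraries of a group, or a cTEC and an mTEC library, came from separate animals. All p-values therefore measure the spread between these libraries, which were treated as independent.

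The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), two-sided, with TMM scaling, all 12 libraries in 1 fit of 4 groups with 8 residual degrees of freedom, and Benjamini-Hochberg adjustment with a threshold of 0.05. There were 6 comparisons: genotype in cTEC, genotype in mTEC, genotype averaged over both, the difference of the genotype effects, and mTEC minus cTEC in each genotype. The adjusted p-values printed are from this test unless another is named. Log2 fold changes are Cre over control, or mTEC over cTEC, and positive values mean higher in the group named first. The difference of effects is the cTEC effect minus the mTEC effect.

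There were 30 gene lists, of which 28 had at least 3 tested members: LXR targets, cholesterol synthesis, fatty acid synthesis, cTEC identity, mature mTEC, immature mTEC, tuft cell, corneocyte (keratinised cell), Aire-dependent antigens, S phase, mitosis, MHC class II, MHC class I, interferon response, epithelial growth receptors, immediate early and stress genes, the unfolded protein response, matrix and fibroblast genes, thymocyte, macrophage and dendritic cell, B cell, endothelial, erythroid, lipid storage, sterol export and storage, ribosomal protein, oxidative phosphorylation and histone genes. Genes encoded in the mitochondrial genome and a list of sex-linked genes had too few tested members, 0 and 2. Some genes stand on more than 1 list. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Members were also adjusted over the list alone. Camera compares a list with the other genes. The alternative fry asks only whether a list's members move, on balance, one way.

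The groups, comparisons, tests, lists and the alternatives chosen for them were fixed before the data were examined. The genes named were set by a rule fixed then too: 12 fixed genes; for each comparison up to 10 genes with the largest fold in each direction among those past the threshold, with a mean of at least 5 CPM, no overlap between the groups and a proper gene name; up to 4 members of each list by p; and genes whose genotype effect differed between the cell types. For 3 against 3 libraries chance alone gives no overlap for 10% of genes. Some genes that met the rule are not reported here. Relb, S100a8 and Kitl were named in their comparisons after their values were seen. Alternatives were DESeq2's size factors, DESeq2 1.42.0, limma voom with quality weights (limma 3.58.1), a robust fit, no filter on low counts, a filter of 5 CPM in 3 libraries, only the 6 libraries compared, and each library left out in turn. Offsets for gene length and GC content, and lists with a library left out, were chosen after seeing the data.

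The test was run on simulated data in which 67 genes had been changed 1.5-fold, 67 2-fold and 66 4-fold. In the simulated cTEC comparison, with 16811 genes in the fit, edgeR recovered 38.8% of genes changed 1.5-fold, 58.2% of those changed 2-fold and 89.4% of those changed 4-fold, and called 9 unchanged genes. In mTEC, with 16804 genes, the shares were 29.9%, 58.2% and 87.9%, with 18 unchanged genes called. For the difference of effects, with 16798 genes, they were 4.48%, 41.8% and 65.2%, with 3 unchanged genes called. Small effects, above all in the difference, were therefore often missed. In mTEC the unchanged genes made up a larger share of the calls than the adjusted p threshold aims for. In cTEC that share was slightly above the threshold, and in the difference it was not. False calls among the mTEC genes may therefore be more frequent than the adjusted p implies. Each comparison was simulated only once, with the same spread per gene in all groups, so these runs cannot rank the comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.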

Results

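Liver X receptors (LXRs) are nuclear receptors that respond to oxysterols and regulate cholesterol efflux and lipid synthesis. RNA from sorted thymic epithelial cells of C57BL6/J mice was counted in 12 libraries. Control libraries carried floxed alleles of LXR alpha (Nr1h3) and LXR beta (Nr1h2), and Cre libraries carried the same alleles with a Cre recombinase driven by FoxN1, a transcription factor of thymic epithelium. There were 3 libraries each of control mTEC (1 to 3), Cre mTEC (4 to 6), control cTEC (7 to 9) and Cre cTEC (10 to 12). cTEC support early T cell development and mTEC display tissue antigens to developing T cells. Total counts lay between 4804697 and 11159013 per library. The design asks what changes in each cell type when the floxed receptor genes are exposed to Cre.

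The first principal component of the 2000 most variable genes held 88.7% of the variance and separated mTEC from cTEC. The next components held 2.92% and 2.25%. Cre cTEC library 11, the one with the fewest counts, lay at -2.47 and -25.6 on these, against 25.8 and 11.6 for library 10 and 12.9 and 1.70 for library 12. Its correlation with library 10 across genes was 0.967, the lowest of any pair within a group.

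Nr1h2 was lower in Cre libraries of both cell types. In cTEC it stood at 172 ± 17.4 CPM in controls and 114 ± 11.3 CPM in Cre (SD, n = 3 each), a log2 fold change of -0.58 (SE 0.13, adjusted p = 0.00566, edgeR). In mTEC the means were 122 ± 11.3 and 78.9 ± 14.6 CPM (log2 fold change -0.63, SE 0.13, adjusted p = 0.0158), and this call was lost without library 2, 3 or 5 (adjusted p up to 0.131). Nr1h3 was low throughout, at 7.67 ± 2.61 against 8.34 ± 1.01 CPM in cTEC and 6.28 ± 0.558 against 7.62 ± 1.68 CPM in mTEC, and did not pass in either (adjusted p = 0.869 and 0.67). A floxed allele loses part of a gene, and counts over whole genes can keep reads from the rest, so these levels do not measure deletion. Foxn1, the gene whose regulatory sequence drives the Cre, was at 270, 353 and 328 CPM in control cTEC and at 73.1, 164 and 94.4 CPM in Cre cTEC (log2 fold change -1.53, SE 0.36, adjusted p = 0.00851, lost with the robust fit). In mTEC it was at 291, 231 and 239 CPM in controls and 155, 33.9 and 57.5 CPM in Cre (log2 fold change -1.63, SE 0.36, adjusted p = 0.0216). The mTEC call for Foxn1 was lost with DESeq2, with the robust fit and without library 1, 3 or 5 (adjusted p up to 0.0997), and without library 4 the value was -2.51.

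**Figure D1:**
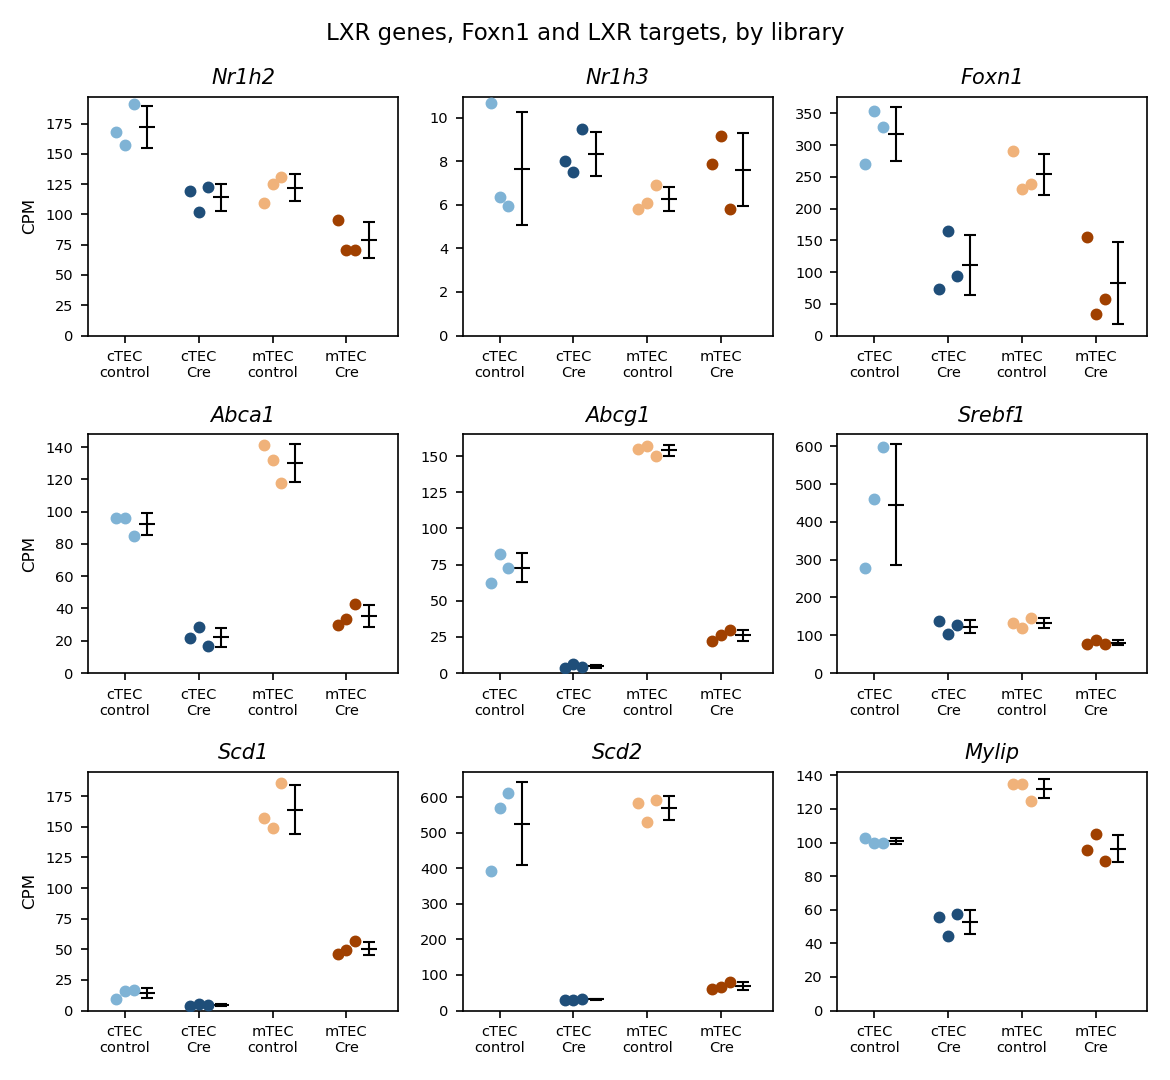
Levels of Nr1h2, Nr1h3, Foxn1 and 6 LXR targets in CPM (vertical axis, from 0) for the 4 groups; each point is 1 library and the bar beside the points is the mean with its SD (n = 3). Abcg1 averaged 72.7 CPM in control cTEC and 4.54 CPM in Cre cTEC, and 154 and 26.1 CPM in mTEC, while Nr1h3 lay below 11 CPM in every library.

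In Cre cTEC, LXR targets and genes of cholesterol and fatty acid synthesis fell. Scd2, a stearoyl-CoA desaturase, went from 526 ± 116 to 31.2 ± 1.48 CPM (SD, n = 3), a log2 fold change of -4.07 (SE 0.17, adjusted p = 2.1e-11, edgeR). The sterol efflux transporters Abcg1 and Abca1 fell by 4.05 (SE 0.17, adjusted p = 2.3e-11) and 2.07 (SE 0.16, adjusted p = 2.7e-07) on the log2 scale. Srebf1, a regulator of fatty acid synthesis, went from 446 ± 160 to 123 ± 18 CPM, Scd1 from 14.1 ± 4.03 to 4.77 ± 0.846 CPM, and Mylip, a ubiquitin ligase gene, from 101 ± 1.96 to 52.5 ± 7.24 CPM (log2 fold changes -1.85, -1.61 and -0.94). Of 20 LXR targets, 9 fell and 11 did not pass (camera adjusted p = 7.0e-23, and adjusted p = 0.000115 with an estimated correlation). Adjusted over the list alone, 10 fell and 1 rose.

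Cholesterol synthesis genes also fell in Cre cTEC: 17 of 25 were lower and 8 did not pass. Fdft1 and Sc4mol, enzymes of the pathway, fell by 2.07 and 1.55 on the log2 scale (SE 0.22 and 0.16), and Cyp51 by 1.12 (SE 0.16). The camera adjusted p was 3.6e-23, and the call was lost with an estimated correlation (adjusted p = 0.0657). Adjusted over the list alone, 21 were lower. Of 22 fatty acid synthesis genes, 9 fell and 13 did not pass, among them Scd2 and Acsl3, an acyl-CoA synthetase (log2 fold change -1.56, SE 0.12). That list had a camera adjusted p of 5.2e-19, and adjusted p = 0.0364 with an estimated correlation, with 12 lower adjusted over the list alone.

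Several genes of cTEC function were higher in Cre cTEC. Of 17 cTEC identity genes, 7 rose, 2 fell (Foxn1 and the chemokine receptor gene Ccrl1) and 8 did not pass. Tbata rose from 713 ± 75.3 to 1600 ± 718 CPM and Ly75, an endocytic receptor, from 476 ± 59.4 to 946 ± 395 CPM. Dll4, the Notch ligand that commits progenitors to the T lineage, rose from 50.8 ± 18.8 to 113 ± 46.7 CPM, a call lost with the robust fit. The thymoproteasome subunit Psmb11 stood at 352 ± 91.8 and 695 ± 313 CPM (log2 fold change 0.98, SE 0.29, adjusted p = 0.0363), and Prss16, a thymus-specific serine protease, at 1930 ± 291 and 3710 ± 1740 CPM (0.94, SE 0.25, adjusted p = 0.0191). In library 11 Psmb11 (370 CPM), Prss16 (1980), Dll4 (64.1) and Tbata (817) stood within or near the control range, and Ly75 (636) above that of 408 to 514 CPM. Psmb11 lost its call without library 7, 9, 10 or 12 and with DESeq2, the robust fit, or length and GC offsets. Prss16 lost its call without library 7, 9 or 10 and with the robust fit. Without library 10 the log2 fold changes were 0.63 for Psmb11, 0.56 for Prss16 and 0.60 for Ly75, with adjusted p of 0.202, 0.138 and 0.0152. The list's camera adjusted p was 0.000213, and the call was lost with an estimated correlation (adjusted p = 0.876). Adjusted over the list alone, 10 rose and 2 fell.

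Genes of immature mTEC, including basal keratins, were mostly lower in Cre cTEC: 7 of 12 fell, 1 rose and 4 did not pass. Krt14 went from 965 ± 93 to 435 ± 7.58 CPM, Krt15 from 56.3 ± 17.7 to 14.1 ± 11 CPM, Cxcr7, a chemokine-scavenging receptor, from 52.9 ± 9.63 to 17.4 ± 4.01 CPM, and Dcn, a matrix proteoglycan, from 2460 ± 234 to 1200 ± 174 CPM. In control mTEC, Krt14, Krt15, Cxcr7 and Dcn averaged 1590, 52, 7.8 and 146 CPM. Cxcr7 and Dcn were thus higher in control cTEC than in control mTEC, and the list does not hold only genes particular to mTEC. The camera adjusted p was 4.0e-10, and the call was lost with an estimated correlation (adjusted p = 0.0536). Adjusted over the list alone, 8 fell and 1 rose. Of 23 growth receptor genes, 5 rose and 18 did not pass: Tnfrsf11a (RANK), Cd40, Map3k14 and Nfkb2 (log2 fold changes 0.83, 1.02, 0.91 and 0.63) and Relb (0.42, lost in the fit to the 6 libraries and without library 7, 8, 9, 10 or 12, and 0.25 without library 10). These belong to the RANK and CD40 receptors and the noncanonical NF-kappa B pathway. All 5 averaged more in control mTEC than in control cTEC. The means were 408 and 20.2 CPM for Tnfrsf11a, 141 and 14.6 for Cd40, and 99.1 and 38.9 for Map3k14. For Nfkb2 they were 419 and 100 CPM, and for Relb 301 and 88.4 CPM. A change within cTEC and more mTEC RNA in the Cre cTEC libraries were not told apart. The list's camera adjusted p was 0.0207, and the call was lost with an estimated correlation (adjusted p = 0.876) and without library 10 (adjusted p = 0.269). Adjusted over the list alone, 5 rose.

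Among 18 mature mTEC genes in Cre cTEC, 4 rose, 2 fell and 12 did not pass (camera adjusted p = 0.48; 5 higher and 7 lower adjusted over the list alone), with Irf8 up by a log2 fold change of 0.70 and Hdc, histidine decarboxylase, down at -1.65. In controls Irf8 averaged 108 CPM in cTEC and 279 in mTEC, and Hdc 15.5 and 480 CPM. The share of mTEC RNA in the cTEC libraries was not estimated. Of 18 tuft cell genes, Alox5 and Ptgs1 fell (log2 fold changes -0.52 and -0.56; list camera adjusted p = 0.14). Alox5 lost its call without library 7 or 10 and Ptgs1 without library 8, 9 or 10 (adjusted p up to 0.0929 and 0.103). Of 18 corneocyte genes, Krtdap fell (-1.15), and Dsg1a and Klk6 rose (1.02 and 4.43; list camera adjusted p = 0.522). Without library 11 the corneocyte list passed as lower (median -0.66 against -0.15, adjusted p = 0.00684). Klk6 was at 45.2 CPM in library 11 and under 0.5 CPM in the other Cre cTEC libraries, and its value was -0.74 without library 11. Klk6 lost its call without library 7, 8, 9 or 11, and Dsg1a without library 7, 9, 10 or 11 (adjusted p up to 0.518 and 0.11). Of 16 Aire-dependent antigen genes, Csn2, Pcp4 and Defb1 fell (-1.96, -1.72 and -0.85), and S100a9 and S100a8 rose from under 1 CPM (2.43 and 3.27; list camera adjusted p = 0.268). S100a9 lost its call without library 7, 8, 9 or 10, and S100a8 without library 7, 8 or 10. Without library 10 their values were 0.78 and 0.87, and without library 9, which leaves controls with 0 counts of S100a8, that of S100a8 was 7.33. Dsg1a, Klk6, S100a9 and S100a8 also lost their calls with voom, Klk6, S100a9 and S100a8 with the robust fit, Klk6 and S100a8 with DESeq2, S100a8 with the stricter filter and Dsg1a in the fit to the 6 libraries, and Alox5 lost its call without a filter. Adjusted over each list alone, the tuft list had 2 lower, the corneocyte list 3 higher and 2 lower, and the Aire-dependent list 2 higher and 3 lower.

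Few genes of proliferation, antigen presentation and stress passed with edgeR in Cre cTEC. Of 30 mitosis genes Cdc20 fell (-0.55, lost without library 7, 8, 11 or 12, adjusted p up to 0.25; no member passed adjusted over the list alone). Of 14 MHC class I genes Nlrc5 rose (0.83) and Psmb10 rose (0.51, lost without library 7, 9, 10 or 12, adjusted p up to 0.151). Of 12 MHC class II genes Ifi30 rose (0.54, lost without the same libraries, adjusted p up to 0.153). Of 26 interferon genes Cxcl10 rose (0.85) and Cxcl9 rose (1.17, lost without library 7, 8 or 11, adjusted p up to 0.0626). Of 20 immediate early genes Fosb rose (1.35, lost without library 7 or 9, adjusted p up to 0.0567). That list had a median log2 fold change of 0.35, 18 of 20 positive values and a camera adjusted p of 0.00072. The call was lost with an estimated correlation (adjusted p = 0.876) and without library 10 (median 0.178, camera adjusted p = 0.0672). Adjusted over the list alone, 3 members rose. Of 19 unfolded protein response genes Trib3 rose (1.18). None of the other lists in this group passed camera with all libraries (adjusted p from 0.0925 to 0.779). Mitosis genes did, toward lower, without library 8, 10 or 11 (adjusted p down to 0.0375) and interferon genes, toward lower, without library 12 (0.0454), and MHC class I and II genes, toward higher, without library 11 (0.0421 and 0.0193). Adjusted over each list alone, 3 MHC class II genes were higher and 1 lower, 2 MHC class I genes were higher, 2 interferon genes were higher and 2 lower, and Trib3 was higher. DESeq2 and voom called 3 and 10 immediate early genes, 4 and 4 of MHC class II, 3 and 4 of MHC class I, 5 and 1 of interferon, 1 and 2 of mitosis and 1 and 2 of the unfolded protein response. The calls for Cdc20, Ifi30, Psmb10 and Cxcl9 were also lost in the fit to the 6 cTEC libraries alone, that for Cxcl9 with voom, that for Fosb with the robust fit, and that for Cdc20 with DESeq2's size factors, without a filter and with length and GC offsets.

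Markers of other cell types and further groups gave few calls in Cre cTEC. Fbn1 and Col3a1 rose and Lum fell among 13 matrix genes (1.33, 0.82 and -1.27), and Col3a1 lost its call without library 7, 8, 11 or 12 (adjusted p up to 0.0989). Bcl11b fell among 22 thymocyte genes (-0.51, lost without library 7 or 9, adjusted p up to 0.0665). Zbtb46 rose and Ctsb fell among 21 macrophage and dendritic cell genes (0.60 and -0.37), calls lost without library 9 for Zbtb46 (adjusted p = 0.0546) and without library 7, 8, 9 or 10 for Ctsb (adjusted p up to 0.156). Plvap fell among 12 endothelial genes (-1.61, adjusted p = 0.0503 without library 9), and Epb4.2 among 7 erythroid genes (-1.18, lost without library 7, 8, 9, 10 or 11, adjusted p up to 0.162). Nceh1 fell and Abca7 rose among 14 sterol export and storage genes (-0.69 and 0.79), the latter lost without library 7 or 10 (adjusted p up to 0.0999). Of the erythroid genes 6 of 7 values were positive, with a median of 2.47 (camera adjusted p = 0.251, and 0.0454 without library 12), and from 0.73 without library 10 to 2.18 without library 9. Cox8b rose among 73 oxidative phosphorylation genes (2.13) but was not called by DESeq2, and Hist1h1c fell among 14 histone genes (-0.81, and -0.53 without library 7). No gene of the S phase, B cell, lipid storage or ribosomal protein lists passed with edgeR, DESeq2 or voom. Of these lists' 121 members, 3 had an unadjusted p under 0.05. All these lists missed the camera threshold with all libraries (adjusted p from 0.14 to 0.912). Without 1 library, beside the erythroid list, those of histone (library 9 or 11, adjusted p = 0.00483 and 0.0421) and endothelial genes (11, 0.0421) passed toward lower and those of matrix (10, 0.0193) and oxidative phosphorylation genes (11, 0.0198) toward higher. Adjusted over each list alone, 4 matrix and 4 erythroid genes were higher and 1 of each lower, and the other lists of this group kept the same counts. Calls were also lost for Col3a1 with the robust fit, for Col3a1, Ctsb and Epb4.2 in the fit to the 6 libraries, for Col3a1, Epb4.2 and Abca7 with length and GC offsets, for Epb4.2 with voom and for Ctsb without a filter. Median and mean differed in sign for the corneocyte, MHC class I, unfolded protein response and sterol export lists.

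In all, 971 genes were higher and 584 lower in Cre cTEC (1555 of 17268), and 3434 had an unadjusted p under 0.05. By at least 2-fold, 183 were higher and 174 lower. The largest increases among genes meeting the naming rule were those of Sec14l5 (from 2.58 ± 0.957 to 15.2 ± 7.43 CPM), Lrat (2.43, SE 0.47), Rnf183, Smtnl2, Atp7b, Cdhr1, Fgf21, Notch3, Lrrc16b and Pde1b (1.91, SE 0.18). Lrat encodes the enzyme that esterifies retinol, and its value was 1.44 without library 12. All genes named here as increases but Atp7b averaged more in control mTEC than in control cTEC, such as Cdhr1 (309 and 4.87 CPM). Some genes that fell did too, such as Reg3g (456 and 39.7 CPM). The largest decreases included, beside Scd2 and Abcg1, those of Ism1 (-2.48, SE 0.28), Mid1ip1, Serpinb2, Chi3l4, Adamtsl5, Reg3g and Krt15 (-2.08, SE 0.32). Chi3l4 has a near-identical copy, Chi3l3, so its counts are uncertain. Genes called higher were long, with a median longest transcript of 5714 bases against 3261 for all genes tested, and with length and GC offsets 717 genes were higher and 573 lower. The count was 1022 without library 7, 1018 without library 9 and 1019 without library 10, and 2294 without library 11.

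**Figure D2:**
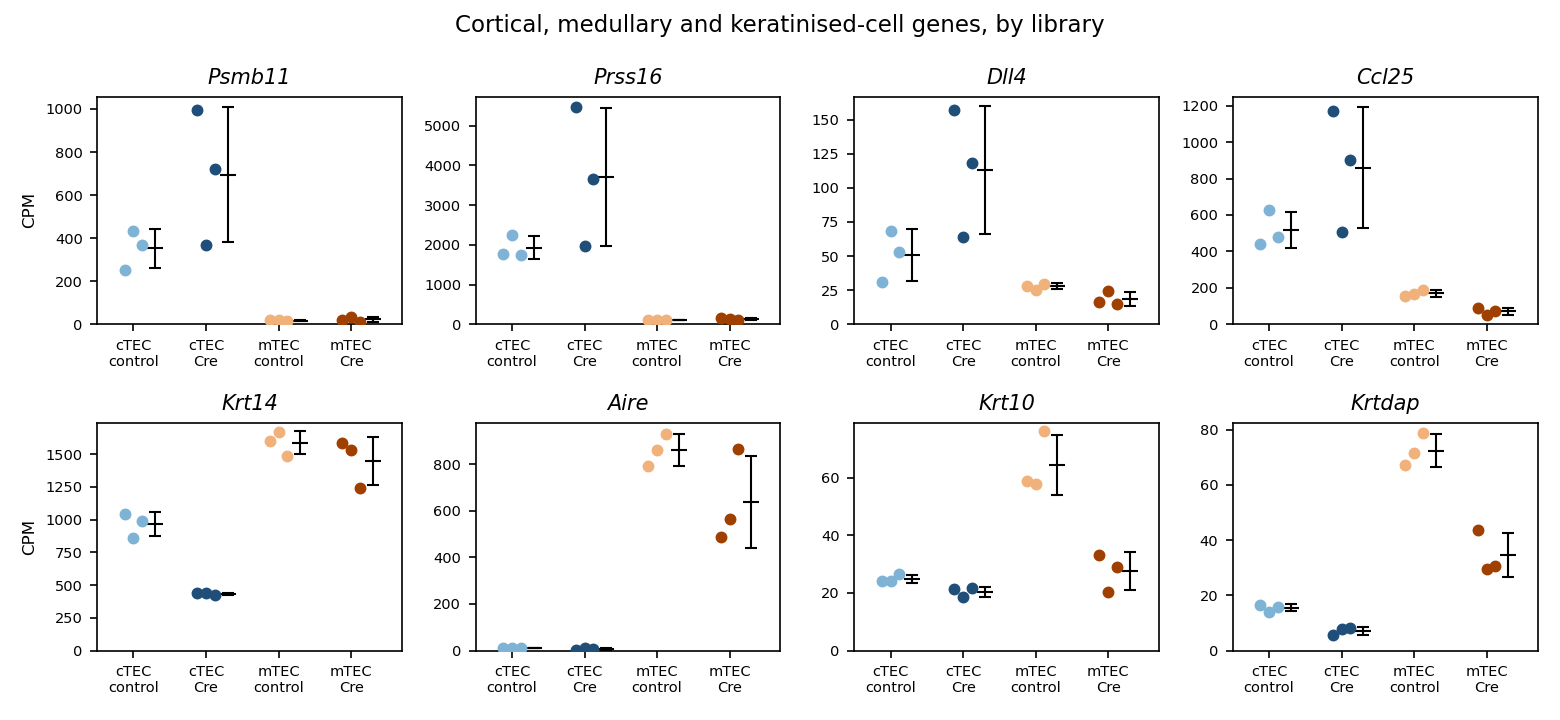
Levels of Psmb11, Prss16, Dll4, Ccl25, Krt14, Aire, Krt10 and Krtdap in CPM (vertical axis, from 0) for the 4 groups; each point is 1 library and the bar beside the points is the mean with its SD (n = 3). Krt14 lay between 427 and 442 CPM in Cre cTEC against 862 to 1040 CPM in control cTEC, and Krt10 averaged 64.4 CPM in control mTEC and 27.7 CPM in Cre mTEC.

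In Cre mTEC, LXR targets and fatty acid synthesis genes fell as well. Scd2 went from 569 ± 33.5 to 68.8 ± 11.1 CPM (SD, n = 3; log2 fold change -3.05, SE 0.16, adjusted p = 1.1e-09, edgeR). Abcg1 went from 154 ± 3.64 to 26.1 ± 3.7 CPM, Abca1 from 130 ± 11.8 to 35.4 ± 6.84 CPM and Scd1 from 164 ± 19.7 to 50.6 ± 5.26 CPM (log2 fold changes -2.56, -1.88 and -1.69). Mylip fell from 132 ± 5.63 to 96.4 ± 8 CPM, a call lost in each of the 6 fits without 1 mTEC library, 1 to 6 (adjusted p from 0.0525 to 0.145). Srebf1, at 133 ± 12.6 and 80.5 ± 6.72 CPM, did not pass (adjusted p = 0.06), but did with DESeq2, DESeq2's size factors, voom, no filter and only the 6 libraries. Of 20 LXR targets, 5 fell and 15 did not pass (camera adjusted p = 5.0e-25, and adjusted p = 7.6e-05 with an estimated correlation), with 8 lower and 1 higher adjusted over the list alone. Of 22 fatty acid synthesis genes, 9 fell and 13 did not pass, including Me1, malic enzyme (-0.87), and Dgat2, an enzyme of triglyceride synthesis (-0.81). The camera adjusted p was 7.7e-25, and adjusted p = 0.0149 with an estimated correlation. Adjusted over the list alone, 11 fell. Of 25 cholesterol synthesis genes, 1 fell and 24 did not pass, although all 25 values were negative. That list had a camera adjusted p of 1.5e-09, lost with an estimated correlation (adjusted p = 0.296), and 11 were lower adjusted over the list alone.

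Genes of corneocytes, the keratinised cells that form late in the mTEC lineage, fell in Cre mTEC. Of 18, 8 fell, 10 did not pass and all 18 values were negative, with a median log2 fold change of -1.07. Krt10 went from 64.4 ± 10.4 to 27.7 ± 6.51 CPM, Krtdap from 72.4 ± 5.94 to 34.6 ± 7.97 CPM and Krt77 from 35.9 ± 7.98 to 15.4 ± 2.74 CPM. Lor, a protein of the cornified envelope, went from 16.6 ± 3.18 to 7.64 ± 0.22 CPM, a call lost without library 1, 3 or 5 (adjusted p up to 0.0979). The camera adjusted p was 3.2e-17, and adjusted p = 0.0398 with an estimated correlation, with 11 lower adjusted over the list alone.

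Of 18 mature mTEC genes, 2 fell and 16 did not pass: Tnfrsf8 (-0.83, lost without library 1, 3 or 5) and Ccl22 (-0.69, lost without library 1 or 5), with adjusted p up to 0.0876 and 0.125. Aire, the regulator of tissue antigens in mTEC, was at 793, 860 and 932 CPM in controls and at 487, 564 and 864 CPM in Cre, and did not pass (log2 fold change -0.43, SE 0.20, adjusted p = 0.322), but did with voom and without library 6 (-0.72, adjusted p = 0.0441). In cTEC Aire was at 10.2 ± 0.506 CPM in controls and 5.72 ± 3.37 CPM in Cre and did not pass (-0.95, adjusted p = 0.0848), but did without library 11 (-1.46, adjusted p = 0.00834), with voom and without a filter, and its value was -0.57 without library 10. The list's camera adjusted p was 3.6e-07, lost with an estimated correlation (adjusted p = 0.0609), with 7 lower adjusted over the list alone and a median of -0.41, or -0.65 without library 6. Of 18 tuft cell genes, L1cam fell (-0.77, lost without library 1, 2, 3, 4 or 5 and with the stricter filter, adjusted p up to 0.289, and -1.18 without library 6) and 17 did not pass. The tuft list's camera adjusted p was 6.7e-06, lost with an estimated correlation (adjusted p = 0.423), with 7 lower adjusted over the list alone. Of 16 Aire-dependent antigen genes none passed with edgeR, 6 had an unadjusted p under 0.05, and DESeq2 and voom called 1 and 7. Its camera adjusted p of 7.2e-05 was lost with an estimated correlation (adjusted p = 0.0931), and 4 were lower adjusted over the list alone. The tuft and Aire-dependent medians were -0.50 and -0.42, beside -0.41 for mature mTEC genes. Outside the corneocyte list, 642 genes at least 8-fold higher in control mTEC than in control cTEC had a median of -0.46. Picking those genes by the same controls can pull that median down. Camera compares a list with the other genes, so these list calls were not told apart from a general fall of mTEC-enriched genes. Of 17 cTEC identity genes, Foxn1 and the chemokine gene Ccl25 fell and the cytokine gene Il7 rose (camera adjusted p = 0.426). Ccl25 went from 169 ± 17 to 70.8 ± 19.2 CPM (lost without library 5, adjusted p = 0.0788, and with the robust fit) and Il7 from 372 ± 33.3 to 556 ± 84.2 CPM (lost without library 1, 2, 3, 4 or 5, adjusted p up to 0.305, and with length and GC offsets). Psmb11 and Prss16 did not pass in mTEC (adjusted p = 0.701 and 0.642). Ly6d was the 1 immature mTEC gene of 12 to fall (-0.91, list camera adjusted p = 0.24, and 0.0128, toward lower, without library 4). Ccl21a, a chemokine gene of immature mTEC, had 3 counts in all 12 libraries and was not tested. The treatment of reads that match several places is not given, so this count does not show that the gene was silent.

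Few other list members passed in Cre mTEC. Trib3 fell among 19 unfolded protein response genes (-0.76, lost without library 1, 2, 3, 4 or 5, adjusted p up to 0.254). That list had a camera adjusted p of 2.0e-05, lost with an estimated correlation (adjusted p = 0.319), with 4 lower adjusted over the list alone. H2-Ob fell among 12 MHC class II genes (-0.65, lost without the same libraries, adjusted p up to 0.144). The class II list's camera adjusted p of 0.00749 was lost with an estimated correlation (adjusted p = 0.692) and without library 5 (adjusted p = 0.0696). Mrc1, a mannose receptor, fell among 21 macrophage and dendritic cell genes (-0.94, lost without library 1 or 5, adjusted p up to 0.07). That list's camera adjusted p of 0.0331 was lost with an estimated correlation (adjusted p = 0.599) and without library 3 or 5 (up to 0.183). Of 22 thymocyte genes none passed with edgeR, DESeq2 or voom and 1 had an unadjusted p under 0.05. The thymocyte camera adjusted p of 0.0376, toward higher, was lost with an estimated correlation (adjusted p = 0.866) and without library 1, 2 or 4 (up to 0.506). Oas2 fell among 26 interferon genes (-0.96, list camera adjusted p = 0.982, lost without library 1, 4 or 5, adjusted p up to 0.134), and Col1a1 among 13 matrix genes (-0.81, list camera adjusted p = 0.545, lost without library 1, 2, 3, 4 or 5, adjusted p up to 0.193). No gene passed with edgeR in the S phase, mitosis, MHC class I, growth receptor, immediate early, B cell, endothelial, erythroid, lipid storage, sterol export, ribosomal protein, oxidative phosphorylation or histone lists, and none of these lists passed camera with all libraries (adjusted p from 0.0872 to 0.982). With a library left out, mitosis genes passed toward lower without library 3 or 6 (adjusted p = 0.0293 and 3.0e-06, with a median of -0.36 without 6 against -0.13). MHC class I genes passed toward lower without library 3 or 4 (down to 0.00758) and with DESeq2's size factors, and oxidative phosphorylation genes toward lower without library 1 (0.0386). Immediate early genes passed toward higher without library 4 (0.000128), and ribosomal protein genes toward higher without library 2 (0.00207) and with length and GC offsets. Adjusted over each list alone, 1 B cell and 1 sterol export gene were lower, 2 erythroid genes were higher and 2 lower, and none of the other 10 lists had a call. Including the thymocyte and Aire-dependent lists, the 15 lists without a call held 366 members, counting repeats, of which 31 had an unadjusted p under 0.05, and DESeq2 and voom called 4 and 20. The erythroid median was 1.51, and -0.75 without library 4. Calls were also lost for Trib3 and Col1a1 with length and GC offsets and for Col1a1 with the stricter filter. Median, mean and camera differed in sign for the cTEC identity, interferon, B cell, erythroid, lipid storage and oxidative phosphorylation lists.

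In all, 101 genes were higher and 257 lower in Cre mTEC (358 of 17268), and 2528 had an unadjusted p under 0.05. By at least 2-fold, 42 were higher and 77 lower. The largest increases among genes meeting the naming rule included those of Stmn2 (1.74, SE 0.21), Frem1, Mfap2, Fbn2, Fbxl22, Adamts20, Clrn1, Lphn3 and Lgi2 (1.12, SE 0.20). Fbn2 lost its call without library 1, 2, 3 or 4, Fbxl22 without library 1, Lgi2 without library 1 or 5, and Adamts20 without any 1 of libraries 1 to 6 (adjusted p up to 0.165) and with the stricter filter. The decreases, beside Scd2, Abcg1, Abca1, Scd1 and Foxn1, included Psors1c2 (-1.80, SE 0.19), Chi3l4, Oxtr, Tmem45a and Fgf14 (-1.51, SE 0.31). Oxtr lost its call without library 1 (adjusted p = 0.0501), and Fgf14 without library 1, 3 or 5 (adjusted p up to 0.11) and with the robust fit. The count of genes moved with every library: 78 without library 1, 180 without 2, 104 without 3, 160 without 4, 81 without 5 and 671 without 6. DESeq2 called 599, voom 1672, the fit without a filter 1049 and the fit to the 6 mTEC libraries 1026.

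**Figure D3:**
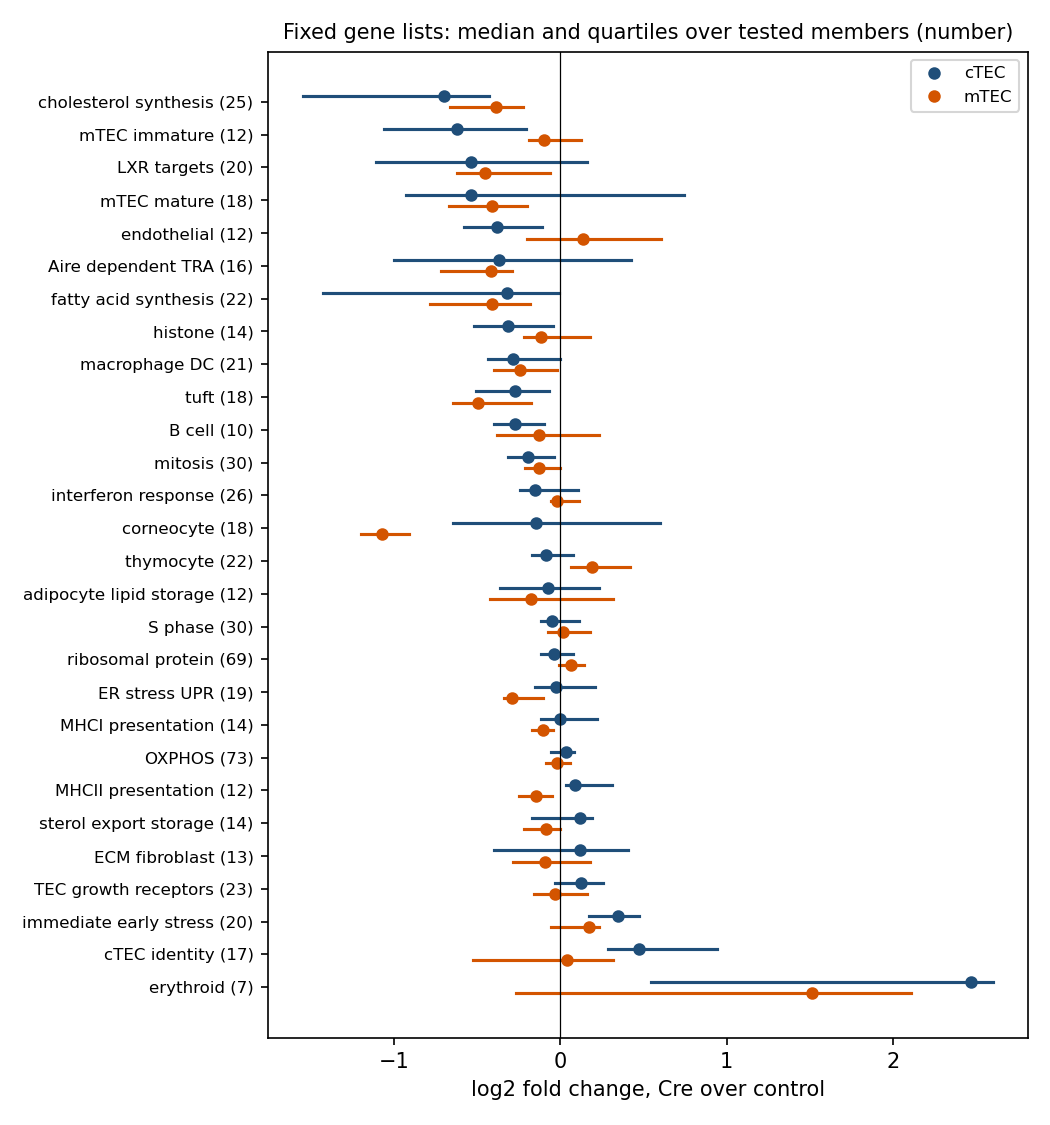
Median log2 fold change, Cre over control, of each gene list (vertical axis) in cTEC and mTEC, with lines between the lower and upper quartiles of the members (horizontal axis, log2). The corneocyte median was -1.07 in mTEC and -0.15 in cTEC (-0.66 without library 11), and that of cholesterol synthesis genes was -0.70 in cTEC and -0.39 in mTEC.

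Averaged over both cell types, with 6 Cre and 6 control libraries, 621 genes were higher and 624 lower (1245 genes), and 3279 had an unadjusted p under 0.05. Among genes meeting the naming rule, the largest decreases included those of Scd2 and Abcg1 (log2 fold changes -3.56 and -3.30), Abca1 (-1.98), Lypd2, Chi3l4, Mid1ip1, Scd1, Klk1b26 and Serpinb2 (-1.60). Among the same genes Stmn2 gave the largest increase (1.90), followed by Lgi2, Dll3, Pde1b (1.24), Frem1 (1.23), Lrrc16b, Nos1, Cdhr1, Gja4 and Syngr1. Nr1h2 (-0.61), Foxn1 (-1.58), Srebf1 (-1.29) and Mylip (-0.70) fell, as did Aire (-0.69, adjusted p = 0.0334), and Prss16 rose (0.63, adjusted p = 0.0344). Lypd2 lost its call without library 8 (adjusted p = 0.117). Aire lost its call without any 1 of libraries 2 to 5, 7 to 10 and 12, and Prss16 without any 1 of libraries 1 to 5, 7, 9, 10 and 12 (adjusted p up to 0.107 and 0.104), and both with DESeq2 and the robust fit. The count of genes was 813 without library 3 and 805 without library 5, and voom called 2065.

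The genotype effect differed between cTEC and mTEC for 692 genes, with a more positive effect in cTEC for 505 and a more negative one for 187. Abcg1 (difference -1.49, SE 0.23), Scd2 (-1.03, SE 0.21) and Srebf1 (-1.13, SE 0.27) fell more in cTEC, although Srebf1 lost the call without library 1, 2, 5 or 9 (adjusted p up to 0.0693). Ccl25 (2.00, SE 0.33), Dll4 (1.77, SE 0.39) and Tbata (1.69, SE 0.32) had more positive effects in cTEC, with the call for Dll4 lost in the robust fit, as were those for Srebf1, Lrat and Me3, and Krt14 a more negative one (-1.02, SE 0.18). The largest positive differences meeting the naming rule were those of Lrat (3.17), Sec14l5 (2.92), Fgf14 (2.47) and Crip3 (2.39). The largest negative ones were those of Sst (-2.92), Ism1 (-2.49), Ptplad2 (-2.23) and Me3 (-2.18). In cTEC Sst was near the floor, at 0.861, 1.34 and 1.99 CPM in controls and 0.112, 0.386 and 0 CPM in Cre. Sst was lost without library 1, 2, 3, 4, 8, 9, 10 or 12, Ptplad2 without library 1, 4, 5, 7, 8 or 10, and Me3 without library 1, 2, 4, 5, 7 or 8 (adjusted p up to 0.134). Neither Foxn1 (0.10), Nr1h2 (0.04) nor Scd1 (0.09) passed this test (adjusted p = 0.953, 0.944 and 0.927). The count was 371 without library 1, 437 without library 3, 457 without 5, 459 without 7, 411 without 9 and 1644 without 11, and DESeq2, voom and the fit without a filter called 1131, 1398 and 1140.

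Of the genes called in either comparison, 64 were lower in both cell types and 19 higher in both. Independent lists would share 8.69 and 5.68 genes (Fisher's exact p = 1.7e-37 and 3.0e-06, two-sided). The 64 included Abca1, Abcg1, Scd1, Scd2, Mylip, Acsl3, Mid1ip1, Nr1h2, Foxn1, Krtdap and Ly6d. The 19 included Stmn2, Lgi2, Pde1b, Clrn1 and Fbxl22. Higher in cTEC and lower in mTEC were 14 genes, Ccl25, Crip3, Fgf14 and Trib3 among them, against 14.5 for independent lists, and 4 were the opposite, Adamts19 among them, against 3.42. Across all 17268 genes the log2 fold changes correlated weakly (Pearson r = 0.132, Spearman rho = 0.104), and genes are not independent replicates. The comparisons share no libraries, but they were fitted together. Whether a cTEC and an mTEC library came from separate animals is not given in the labels. Shared animals could add to the overlap, so the Fisher p-values hold only if the comparisons are independent.

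**Figure D4:**
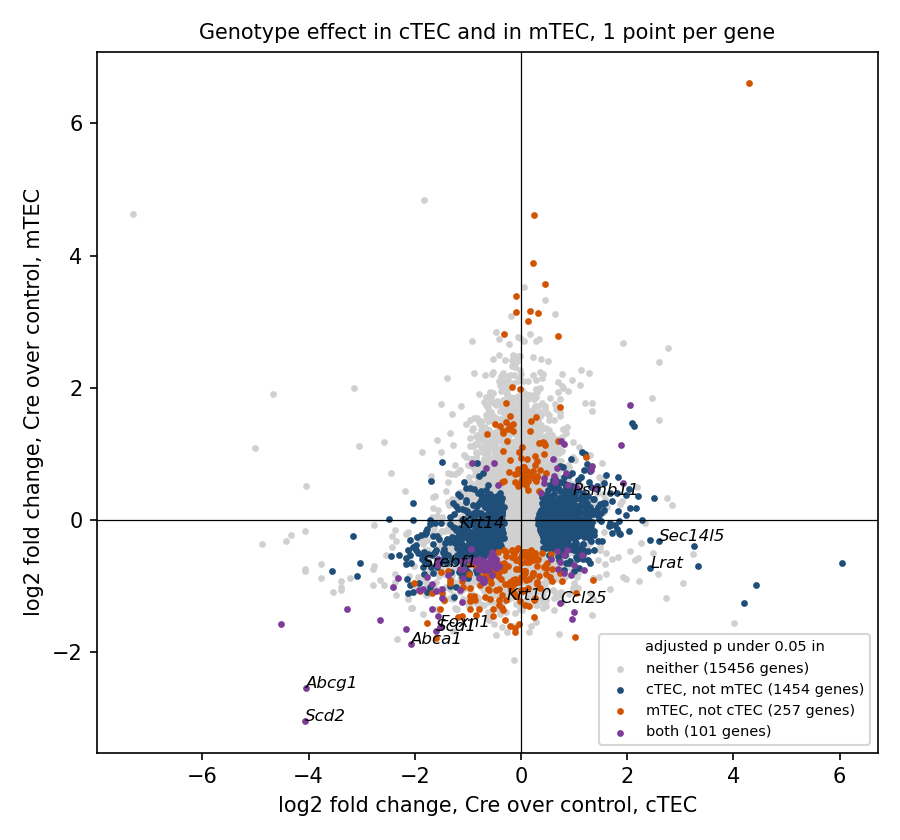
Log2 fold change, Cre over control, in cTEC (horizontal axis) and mTEC (vertical axis), with 1 point per gene tested (17268) and colour showing where the adjusted p was under 0.05. Scd2 lies at -4.07 and -3.05 and Abcg1 at -4.05 and -2.56, while Krt14 (-1.15) moved along the cTEC axis and Krt10 (-1.21) along the mTEC axis.

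Control mTEC and control cTEC differed in the genes that mark each cell type. Aire was at 862 ± 69.6 CPM in mTEC and 10.2 ± 0.506 CPM in cTEC (SD, n = 3; log2 fold change 6.39, adjusted p = 4.1e-13, edgeR), and Psmb11 at 17.4 ± 1.59 and 352 ± 91.8 CPM (-4.33). All 18 mature mTEC genes, 17 of 18 corneocyte, 16 of 18 tuft, 14 of 16 Aire-dependent and 29 of 30 mitosis genes were higher in control mTEC, and 15 of 17 cTEC identity genes were lower. The same counts held adjusted over the lists alone. With an estimated correlation only the mature mTEC list kept its camera call of these lists (adjusted p = 0.00321), against adjusted p = 0.246, 0.546, 0.0778, 0.546 and 0.246 for the corneocyte, tuft, Aire-dependent, mitosis and cTEC identity lists. Of 30 S phase genes 17 were higher and 2 lower (camera adjusted p = 0.0478, lost without library 1 or 7, and adjusted p = 0.77 with an estimated correlation). Of 12 immature mTEC genes 7 were higher and 4 lower (camera adjusted p = 0.669). Macrophage and dendritic cell genes (12 of 21 higher, 2 lower) and B cell genes (7 of 10 higher) had a camera adjusted p of 0.0292, lost with an estimated correlation (adjusted p = 0.546). Of 22 thymocyte genes 13 were lower (camera adjusted p = 0.0584), and that list did not pass with an estimated correlation either. It passed camera without library 3, 7 or 8 (adjusted p from 0.0141 to 0.0475) and passed with fry (adjusted p = 0.0221). Of 12 MHC class II genes 7 were higher and 2 lower (camera adjusted p = 0.0357, lost with length and GC offsets, and adjusted p = 0.786 with an estimated correlation). In all, 5052 genes were higher and 5179 lower in control mTEC (10231 genes). The largest increases included S100a8 (7.45, and 11.5 without library 9, which leaves cTEC controls with 0 counts), Ang4 (6.92), Pyy (6.54), Fgf21 (6.48) and Scgb1a1 (6.29), and the largest decreases Aldh1a1 (-6.48), Prss23 (-6.46), Scn1a (-6.18), Serpinf1 (-5.87) and Ccrl1 (-5.72).

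In Cre libraries 4339 genes were higher and 4234 lower in mTEC than in cTEC (8573 genes). Aire was at 638 ± 199 and 5.72 ± 3.37 CPM (SD, n = 3; log2 fold change 6.90, adjusted p = 5.5e-13, edgeR), Psmb11 at 22.8 ± 11.7 and 695 ± 313 CPM (-4.94) and Prss16 at 137 ± 33.3 and 3710 ± 1740 CPM (-4.76). The largest increases included Csn2 (7.59), Crabp1 (7.06), Ighg1 (6.78), Ang4 (6.74) and Lyz1 (6.50), and the largest decreases Aldh1a1 (-6.40), Il33 (-5.84), Serpinf1 (-5.73), Prss23 (-5.53) and Scn1a (-5.37). Ighg1, an immunoglobulin gene, varied widely between the Cre mTEC libraries, at 28.6, 1.65 and 22.2 CPM. Nr1h3 did not pass in either genotype.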

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

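The test with length and GC offsets, the tests of Foxn1 with their gene lists, and the test of mTEC-enriched genes below were chosen after the results were seen. The genotype effect differed between cTEC and mTEC for 692 genes by edgeR's test of the difference, which is the cTEC effect minus the mTEC effect in log2 units. Lipid genes with a more negative effect in cTEC were Abcg1 (-1.49), Scd2 (-1.03), Srebf1 (-1.13), Mid1ip1 (-1.38), Fdft1 (-1.41), Fads1 (-1.14), Acsl3 (-0.967), Sc4mol (-0.89) and Nceh1 (-0.589), while Me1 (0.862) and Abca7 (1.12) had a more positive one. Without library 1, 2, 5 or 9 the call for Srebf1 was lost (adjusted p up to 0.0693). That for Sc4mol was lost without any 1 of libraries 1, 2, 4 to 6, 8 to 10 and 12 (up to 0.133), that for Nceh1 without any 1 of libraries 1 to 7, 9 and 10 (up to 0.109) and that for Abca7 without library 7 (0.0575). Calls were also lost for Srebf1 with the robust fit, for Sc4mol with DESeq2's size factors and the stricter filter, for Nceh1 without a filter, and for Sc4mol, Nceh1 and Abca7 with length and GC offsets.

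Identity and signalling genes with a more positive effect in cTEC were Ccl25 (2.00), Dll4 (1.77), Tbata (1.69), Ly75 (1.19), Kitl (0.90), Tnfrsf11a (0.859), Cd40 (1.23), Map3k14 (1.11), Nfkb2 (0.816), Irf8 (1.07), Fezf2 (0.957), Nlrc5 (1.05), H2-Oa (0.921), Cxcl9 (1.20), Cxcl10 (1.1), Zbtb46 (0.869), Trib3 (1.94), Hyou1 (0.723), Krt10 (0.935), Lor (2.16), Fbn1 (1.65), Col1a1 (1.55) and Col3a1 (1.58). Those with a more negative effect were Krt14 (-1.02), Cxcr7 (-1.58), Dcn (-1.29), Lum (-1.35), Hdc (-1.28) and Csn2 (-1.70). Calls were lost for Ly75 without library 1, 4, 7 or 9 (adjusted p up to 0.0896), Kitl without library 1, 2, 5, 6, 7, 9 or 10 (up to 0.138), Nfkb2 without library 9 (0.0524), H2-Oa without library 3, 5, 7 or 9 (up to 0.0656), Cxcl9 without library 1, 2, 3, 5, 7, 8, 9 or 11 (up to 0.119) and Krt10 without library 3, 5 or 7 (up to 0.0682). They were also lost for Hyou1 without library 1, 2, 3, 4, 5, 7, 9, 10 or 12 (up to 0.139), Lum without library 3, 4, 5 or 9 (up to 0.093) and Csn2 without library 8, 9 or 10 (up to 0.11). Other alternatives that ended calls were the robust fit (Dll4, Ly75, Col3a1, Lum), voom (Cxcl9, Csn2), the stricter filter (Cxcl9) and length and GC offsets (Ly75, Hyou1, Lum, Csn2).

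Among the genes with the largest changes, positive differences were those of Lrat (3.17), Sec14l5 (2.92), Fgf14 (2.47), Crip3 (2.39), Spp1 (2.28), Rnf183 (2.28), Fgf21 (2.20), Spnb1 (2.09), Kndc1 (2.04), Atp7b (2.00), Notch3 (1.91), Cdhr1 (1.87), Smtnl2 (1.85), Lrrc16b (1.60), Dll3 (1.57), Oxtr (1.53), Tmem45a (1.41), Gja4 (1.40) and Pde1b (1.36). Negative ones were those of Sst (-2.92), Ism1 (-2.49), Ptplad2 (-2.23), Me3 (-2.18), Ttpa (-1.94), Adamts19 (-1.78), Arhgap20 (-1.78) and Efemp1 (-1.72). Sst was near the floor in cTEC, at no more than 1.99 CPM in controls and 0.386 CPM in Cre. Calls were lost for Spp1 without library 8 (adjusted p = 0.0544), Sst without library 1, 2, 3, 4, 8, 9, 10 or 12 (up to 0.134), Ptplad2 without library 1, 4, 5, 7, 8 or 10 (up to 0.116), Me3 without library 1, 2, 4, 5, 7 or 8 (up to 0.117) and Arhgap20 without library 1, 2, 4, 5 or 7 (up to 0.121). Those for Lrat and Me3 were also lost with the robust fit and that for Spp1 with voom.

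By list, camera found differences for LXR targets (median -0.143, adjusted p = 0.0488), cholesterol synthesis (-0.435, 9.6e-05), cTEC identity (0.538, 0.000133), immature mTEC (-0.42, 9.6e-05), corneocyte (0.903, 0.00134), MHC class II (0.285, 0.00235), MHC class I (0.128, 0.0445), growth receptor (0.0589, 0.0342), immediate early (0.171, 0.0445) and unfolded protein response genes (0.157, 0.00151). None of these calls held with an estimated correlation, where adjusted p ran from 0.465 to 0.855, or with fry, where it ran from 0.115 to 0.667. The LXR target call was lost without any 1 of libraries 1, 2, 3, 5, 6 and 8 to 12 (adjusted p up to 0.176; median -0.0903 without library 5). That of corneocyte genes was lost without library 11 (median 0.281, adjusted p = 0.342). Lost too were the calls for MHC class I genes without library 1, 2, 5, 7, 10 or 12 (up to 0.123; median 0.0691 without library 10), growth receptor genes without library 1 or 10 (up to 0.174; median 0.0291 without library 10) and immediate early genes without library 2, 4, 7, 10 or 12 (up to 0.407; medians 0.0826 without library 4 and 0.073 without library 10). Medians that moved while the call held were those of cholesterol synthesis (-0.173 without library 9, -0.238 without 11), cTEC identity (0.28 without library 10), MHC class II (0.433 without 11), MHC class I (0.197 without 4, 0.24 without 11), unfolded protein response (0.24 without 6, 0.282 without 8, 0.334 without 11) and immediate early genes (0.369 without 11). Growth receptor medians were 0.115 without library 3, 0.202 without 4, 0.117 without 5, 0.0155 without 6, 0.109 without 8 and 0.189 without 11.

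Genes called higher in Cre cTEC were long, with a median length 1.75 times that of all genes tested. Offsets for length and GC content took the correlation of log2 fold change with length from 0.201 to 0.00898 across genes. They were fitted in each library to remove such trends, so this fall is no test. Libraries of 1 group differed with length too. The correlation of length with a library's log CPM relative to its group mean was 0.172 for control cTEC library 7 and -0.148 for library 9. In Cre cTEC it was 0.124 for library 11 and -0.24 for library 12. With them 69.21% of the 971 stayed called (exact 95% interval 66.2 to 72.1), and the ratio of medians was 1.39. The interval takes genes as independent, which they are not, and does not measure the spread between libraries. The share kept argues against such a trend as the source of all the calls. The median length of genes called higher was at least 1.479 times that of all genes tested in the fits without library 10, 11 or 12, which argues against 1 Cre library as the source. For the calls that ended a length or GC bias stays open, and a genotype effect on long genes was not tested.

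Foxn1 was lower in Cre cTEC and Cre mTEC (log2 fold changes -1.53 and -1.63). A lower share of epithelial cells would lower other epithelial genes alike, but 11 of them, 3 also on the cTEC identity list and 3 on other lists, had medians of 0.2265 in cTEC (quartiles 0.0171 and 0.288) and 0.04145 in mTEC (-0.0576 and 0.0839). A set of 6 known FOXN1 targets had medians of 0.8421 in cTEC (quartiles 0.515 and 0.972; 0.504 without library 10) and -0.1065 in mTEC (-0.585 and 0.358), but all 6 are on the cTEC identity list, whose values had been seen, so lower FOXN1 activity stays open in both. In cTEC that list had a median of 0.475, and 0.283 without library 10, and its camera call (adjusted p = 0.000213) was lost with an estimated correlation (adjusted p = 0.876) and with fry (adjusted p = 0.29). Since 0 libraries carried the Cre without floxed receptor genes, an effect of the Cre allele on Foxn1's own transcript and an effect of the receptor genes cannot be told apart.

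Corneocyte genes were lower in Cre mTEC, with a list median of -1.07. Admixture of cTEC RNA was estimated at 0.455% (quartiles -0.018 and 1.39; 29 cTEC-specific genes), where 52.25% would be needed. A lower share of mTEC in general would lower mTEC-enriched genes as much, but 642 genes at least 8-fold higher in mTEC by the controls alone had a median of -0.4612 (quartiles -0.738 and -0.2). The same controls picked these genes and entered the fold change, which by itself can pull that median down. Without library 4, 5 or 6 the list median stayed at or below -0.9645, which argues against 1 Cre library. A genotype effect on keratinised cells or their number stays open and was not tested apart from other causes.

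Other splits of the libraries were tried for each count. For genotype in cTEC, genotype in mTEC, and mTEC against cTEC in control and in Cre libraries, 10 splits are too few for a share under 0.05. The real split gave 1555, 358, 10231 and 8573 genes, and the highest other gave 0, 1, 0 and 0. For the averaged comparison only 1 of 100 splits, the real one, reached 1245 genes, and the highest other gave 692. The latter split exchanges the genotypes within 1 cell type and so turns the averaged comparison into the difference. It is not a level reached without a genotype effect. The 100 splits were a sample of those possible. A share of 1 of 100 is under 0.05, which makes chance unlikely if the 12 libraries are independent. The labels do not settle that, so chance is not excluded. For the difference 2 of 100 splits reached 692 and the highest other gave 1245, in the split that exchanges the genotypes within 1 cell type and so turns the difference into the averaged comparison. These splits remove the effect of genotype in both cell types, so they do not test whether the effects are equal.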

How the results depend on the processing

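The offsets for gene length and GC content, and the lists with a library left out, were chosen after the data were seen. Of 246 calls for named genes, 201 kept direction and side of the threshold in every alternative that kept all libraries of the comparison, and 184 in every fit with 1 library left out. Of 38 list calls, 6 and 27 did so. Depth limits genes near the floor, where 1 count was up to 0.194 CPM. The cause of the changes below was not tested, except that fewer genes or libraries entered some fits.

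Genes changed in mTEC numbered 599 with DESeq2, 1672 with voom, 1049 without a filter and 1026 with only the 6 libraries. The averaged comparison gave 2065 with voom, and the difference 1131 with DESeq2, 1398 with voom and 1140 without a filter. With voom Klk6 in cTEC was at -0.0266 and Nr1h3 in the difference at 0.0186. With length and GC offsets Nr1h2 in the difference was at -0.0374. List directions that turned, given as medians, were those of S phase (0.0185), lipid storage (-0.067) and ribosomal protein genes (0.0238) in cTEC and interferon (-0.0166), oxidative phosphorylation (0.0326) and histone genes (-0.0405) in mTEC with these offsets; interferon (-0.0622), erythroid (1.47) and histone genes (-0.157) in mTEC with DESeq2's size factors; and interferon genes in mTEC with fry (-0.0209).

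With 1 library left out, counts ran from 1018 to 2294 in cTEC, 78 to 671 in mTEC, 805 to 1815 averaged and 371 to 1644 for the difference. Genes that turned in at least 1 such fit ranged as follows. In cTEC, Klk6 ran from -0.744 to 5.45 and Nr1h3 from -0.0217 to 0.443, and in mTEC Psmb11 from -0.108 to 0.661. In the difference, Foxn1 ran from -0.267 to 0.998, Nr1h2 from -0.0265 to 0.256, Nr1h3 from -0.302 to 0.162 and Scd1 from -0.124 to 0.237. Between mTEC and cTEC, Nr1h3 ran from -0.441 to 0.0675 in controls and -0.296 to 0.0207 in Cre.

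Lists whose direction by camera turned had these ranges of medians. In cTEC they were B cell (-0.606 to -0.103), matrix (-0.299 to 0.204), unfolded protein response (-0.116 to 0.0532), oxidative phosphorylation (-0.0477 to 0.125), S phase (-0.154 to 0.0432), lipid storage (-0.0921 to 0.158), corneocyte (-0.659 to 0.148), ribosomal protein (-0.105 to 0.064), sterol export (-0.0403 to 0.153) and thymocyte (-0.21 to 0.195). In mTEC they were B cell (-0.177 to -0.0636), oxidative phosphorylation (-0.087 to 0.0368), growth receptor (-0.0565 to -0.0112), cTEC identity (-0.155 to 0.149), erythroid (-0.753 to 2.13), histone (-0.251 to 0.0456), immediate early (-0.00892 to 0.246), interferon (-0.109 to 0.0436) and ribosomal protein (-0.0263 to 0.116).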

Other observations

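Fewer genes differed between mTEC and cTEC in Cre than in control libraries (8573 and 10231). A hypothesis was that the cell types lie less far apart in Cre libraries, tested by the slope across genes of the Cre difference on the control difference. The slope was 0.9185 over 12354 genes, from 0.884 to 0.9987 with 1 library left out. The highest value came without library 11, so this stays open.

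Globin transcripts, a sign of red blood cells, varied within groups and were highest in 3 Cre libraries: Hbb-b1 stood at 63 CPM in library 4, 35.8 in library 10 and 13.9 in library 11, and at no more than 8.86 CPM in the others. Its means were 2.6 ± 1.5 and 17.7 ± 16.5 CPM in control and Cre cTEC and 3.89 ± 4.37 and 22 ± 35.5 CPM in mTEC (SD, n = 3). Globin genes have near-identical copies, which makes the count of any single copy uncertain. Xist was between 69.7 and 235 CPM in all libraries, and Ddx3y, Uty and Eif2s3y had 1, 3 and 2 counts over the 12 libraries.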
